A study of Mus musculus with 9 samples.

How the data were processed

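RNA sequencing was done on kidney cortex of 9 male C57/BL6 mice, 5 fed and 4 fasted for 16 h, with 1 library per mouse, per the labels. About 50 mg of cortex was extracted with TRIzol and made into TruSeq libraries, per the labels' protocols. The labels give no batch, litter, pairing or time of collection. FastQC, TopHat2 2.0.9, HTSeq 0.9.1 and DESeq2 are named per the submitters' processing notes, which give 3.5 as the DESeq2 version and name both mm10 and hg19 as builds. The gene annotation used for counting is not stated there.

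The deposited signal in the 9 sample columns is read counts divided by 1 size factor per library, by the authors. This was tested on the file: all 161194 values above 0 are whole multiples of their column's step within a tolerance of 0.01 reads, so the reads were recovered. The deposited log2 fold changes and their standard errors come from the authors' fit and are pulled towards 0. The deposited score column is the log2 fold change over its standard error. The deposited p-value and adjusted p-value are the authors', and are blank for some genes, among them genes that have a score. The deposited annotation tables give the fold enrichment of each term, as the share of the authors' list over that of the background, with a p-value and its Benjamini adjustment. The genes annotated had an adjusted p under 0.01 in the authors' table, as tested on the files (1277 of the 1281 names were found there).

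The recovered reads per library lay between 18902645 and 32469467, which makes 1 read worth between 0.744 and 1.32 normalized counts. Spread between libraries exceeded counting error: chi-square per degree of freedom lay between 16.7 and 117 over the 16 pairs of libraries within a group. Pairs with Fed 3 had the highest values (78.9 to 117), and the other pairs had at most 45.5. Fed 3 had 5.53% of its counts in the ribosomal RNA entry Rn45s, which was kept in this sum. In a principal component analysis the first component held 34.39% of the variance, on which fasted libraries lay from 16.3 to 29.9 and fed libraries from -40.8 to -0.12, and the next held 23.77%.

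The main test was limma 3.58.1 with a trend on log2(value + 1), two-sided, in R 4.3.3, over genes with a mean of at least 10 normalized counts. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The 27 gene lists and 18 marker lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over the lists of each kind. Counts of gene list members are given over all genes tested and adjusted over the list alone. The named genes followed a rule fixed before the data were examined: the 12 largest increases and 12 largest decreases among called genes with a mean of at least 100, the 6 smallest p-values, and up to 4 members of each gene list with the smallest adjusted p. Predicted, unnamed and pseudogene names were left out of the first part. Some genes that this rule names are not reported here, and they stay in the counts over lists and over all genes but not in the search for libraries far from their group. Gene positions were taken from GENCODE M21 on GRCm38 by Ensembl identifier (124 of 125 named genes matched).

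The steps were tested on simulated data with 200 of 15105 genes changed: 96% were recovered at 2-fold and 100% at 4-fold, with 8 false calls among 204, and 0 calls without changes. The simulation drew each gene independently, with a spread between mice that was assumed and not estimated from these libraries. It therefore tests the steps and not the error or sensitivity in these data. Alternatives tried were other filters, pseudocounts, normalizations, thresholds, set tests and backgrounds, voom with and without quality weights, 1 surrogate variable (sva 3.50.0), subsets of the fed mice and each library left out. Added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, TMM, covariates for log2 Alb and for clock phase, and a fit without Fed 3 and Fasted 1. The clustered version of the annotation terms was not used here, and the number of sample columns left unused was 0.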

Results

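Gene expression was measured by RNA sequencing in the kidney cortex of male C57/BL6 mice that had either eaten freely (5 mice, the fed group) or gone without food for 16 h (4 mice, the fasted group). The comparison asks which kidney transcripts differ after such a fast. Each library comes from a cortex piece of about 50 mg from 1 mouse. The reads counted per library, recovered from the deposited values, lay between 19638174 and 32469467 in the fed group and between 18902645 and 27186745 in the fasted group. The table lists 23420 genes, of which 15098 had a mean of at least 10 normalized counts and were tested. Levels below are normalized counts, given as the group mean ± SD with n = 5 fed and n = 4 fasted mice. Changes are on the log2(value + 1) scale, fasted over fed, with the standard error (SE), and adjusted p-values are from limma.

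In the fasted kidneys, transcripts for burning fatty acids were higher, and transcripts for making cholesterol were lower. With an estimated correlation between members the fatty acid oxidation list still passed (camera, adjusted p = 0.030) and the cholesterol list did not (0.32). Pdk4, a kinase that shuts off pyruvate dehydrogenase, rose by 4.59 (SE 0.31) on the log2 scale, from 582 ± 324 to 12504 ± 751 (adjusted p = 2.98e-05). The largest decrease among called genes with a mean of at least 100 normalized counts, predicted, unnamed and pseudogene names left out, was that of Hsd3b2. This steroid dehydrogenase gene fell from 3315 ± 893 to 704 ± 174, a log2 change of -2.23 (SE 0.20, adjusted p = 0.000154). Altogether 1656 genes changed, 863 of them higher and 793 lower in the fasted group, and of these 144 were at least 2-fold higher and 93 at least 2-fold lower. edgeR's quasi-likelihood test on the recovered reads called 1655 genes, 1620 of them among the 1656. DESeq2 on the same reads called 2348, and voom with quality weights called 2704. The count was 861 without Fasted 4, 1004 without Fed 1, 1062 without Fasted 3 and 1084 without Fasted 1, and with Fed 4 and Fed 5 as the only fed mice it was 357. With these fed mice only, 49 of the 92 called genes that a rule named did not pass. Among them were Slc34a1 (adjusted p = 0.34), Calr (0.25), Idi1 (0.21), Sdf2l1 (0.17), Scd2 (0.13), Hsd3b4 (0.12), Nqo1 (0.12) and Pde6a (0.11). Igf2bp1 (0.085), Sc4mol (0.085), Slc16a7 (0.076), Sqstm1 (0.070), Pcx (0.068), Kcnip2 (0.057) and Kl (0.050) did not pass either. It was 1068 without Fed 3 and Fasted 1, an alternative chosen after seeing the data, because these libraries had the highest share of the ribosomal RNA entry Rn45s (5.53% and 2.36% of normalized counts, against 0.513% to 1.38% in the others).

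**Figure D1:**
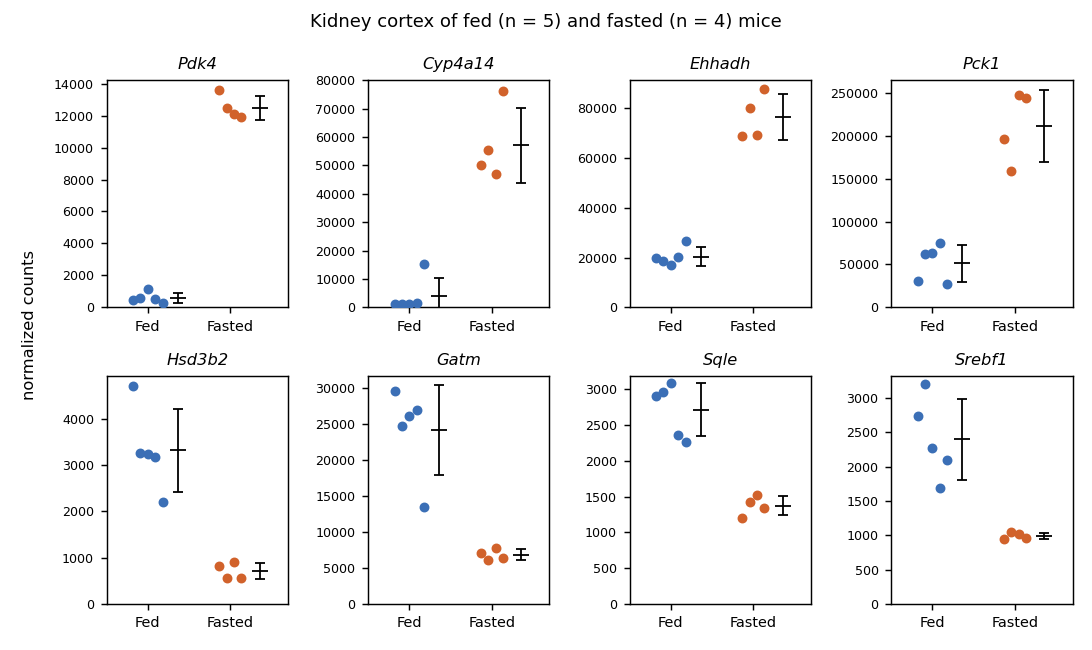
Normalized counts (vertical axes, linear, from 0) of 8 genes in each fed and fasted library, with the group mean and SD as a bar beside the points (n = 5 fed, n = 4 fasted). Pdk4, Cyp4a14, Ehhadh and Pck1 were higher and Hsd3b2, Gatm, Sqle and Srebf1 lower in the fasted group, and Fed 5 stands above the other fed libraries in Cyp4a14.

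Targets of PPAR alpha, the nuclear receptor that switches on fat burning during food shortage, rose as a group: 22 of the 24 measured rose and none fell, and 23 rose when adjusted over the list alone (camera, adjusted p = 5.19e-30; adjusted p = 0.030 with an estimated correlation). Beside Pdk4, the list holds Cyp4a14 and Cyp4a10, which hydroxylate the far end of fatty acids. Cyp4a14 went from 3986 ± 6294 to 57166 ± 13195 (log2 change 4.85, SE 0.68, adjusted p = 0.00157) and Cyp4a10 from 4726 ± 3221 to 28130 ± 2863 (2.77, SE 0.33, adjusted p = 0.000583). The wide fed spread of these genes comes from 1 library. Fed 5 had 15244 normalized counts of Cyp4a14 and 10391 of Cyp4a10, while the other fed libraries had at most 1379 and 4166. Without Fed 5 the log2 changes were 5.59 and 3.10. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 3.03 (SE 0.32, adjusted p = 0.000314). Acot2, a mitochondrial acyl-CoA thioesterase, rose by 2.22 (SE 0.15, adjusted p = 2.45e-05). Cyp4a and Acot genes lie in families of near-identical copies, so reads may be divided among neighbours and their single values are uncertain.

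Of 28 measured genes of fatty acid oxidation 23 rose, 5 did not pass and none fell, and 25 rose when adjusted over the list alone (camera, adjusted p = 4.08e-27; adjusted p = 0.030 with an estimated correlation). Slc25a20, which carries acylcarnitines across the inner mitochondrial membrane, rose from 1191 ± 116 to 3534 ± 426 (log2 change 1.57, SE 0.09, adjusted p = 1.55e-05). Cpt2, the carnitine acyltransferase on the inner side, rose by 1.13 (SE 0.07) with the same adjusted p. Ehhadh, a peroxisomal enzyme of the same pathway, rose from 20438 ± 3768 to 76624 ± 9161 (1.92, SE 0.13, adjusted p = 3.04e-05), and Decr1, which handles unsaturated fatty acids, by 1.05 (SE 0.07, adjusted p = 2.31e-05). The smallest p of any gene belonged to Hsdl2, a peroxisomal short-chain dehydrogenase, which rose from 1658 ± 94.2 to 3878 ± 217 (1.23, SE 0.06, adjusted p = 9.42e-06).

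Genes of fat uptake, triglyceride synthesis and lipid droplets were higher in the balance: 18 of 41 measured rose and 1, Agpat1, fell, against 25 and 4 when adjusted over the list alone (camera, adjusted p = 7.52e-10; adjusted p = 0.18 with an estimated correlation). The lipid droplet coat genes Plin2 and Plin5 rose by 2.42 (SE 0.28, adjusted p = 0.00057) and 2.23 (SE 0.19, adjusted p = 9.63e-05). Plin2 went from 1705 ± 183 to 10326 ± 6716, a wide fasted spread that comes from 1 library. Fasted 2 had 20357 normalized counts of Plin2, and the other fasted libraries had 6181 to 7662. Lipe, hormone-sensitive lipase, rose from 354 ± 41.4 to 897 ± 66.7 (1.35, SE 0.09, adjusted p = 3.04e-05). Acsl1, which activates fatty acids for oxidation or storage, rose by 1.11 (SE 0.10, adjusted p = 0.000154). Some adipocyte markers, named here after their values were seen, rose as well: Plin1 from 0.368 ± 0.823 to 22.4 ± 32.4 (adjusted p = 0.027) and Fabp4 from 597 ± 99.9 to 951 ± 141 (adjusted p = 0.0089). Plin1 reached the mean of at least 10 needed for testing only through the fasted group, where its SD exceeds its mean. Car3 had 1242 ± 635 and 337 ± 108 without passing (adjusted p = 0.062). Of the 4 adipocyte markers measured 2 rose, or 3 with 1 lower when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.24; fry, adjusted p = 0.064, unadjusted 0.0080). Whether fat tissue in the pieces adds to the lipid droplet genes was not tested. In the ketone body list 2 of 10 measured genes rose and 1 fell (3 and 2 when adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.83). The carrier Slc16a1 rose by 1.20 (SE 0.32, adjusted p = 0.035) and the carrier Slc16a7 fell by 0.41 (SE 0.08, adjusted p = 0.0084). The Slc16a1 call was lost without Fed 4 (adjusted p = 0.065), Fasted 1 (0.085), Fasted 2 (0.099) or Fasted 3 (0.064), and in 9 of 27 alternative settings in all.

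Cholesterol synthesis and uptake went the other way. Of 25 measured genes 16 fell and none rose, 18 when adjusted over the list alone (camera, adjusted p = 1.11e-12; adjusted p = 0.32 with an estimated correlation). Sqle, which makes squalene epoxide, fell from 2717 ± 373 to 1376 ± 138 (log2 change -0.98, SE 0.11, adjusted p = 0.000424), and Idi1, an isomerase of the mevalonate route, from 228 ± 95.7 to 64.7 ± 9.42 (-1.66, SE 0.35, adjusted p = 0.0127; 0.065 without Fed 3 and Fasted 1). Sc4mol, a sterol oxidase of cholesterol synthesis, fell by 1.51 (SE 0.29, adjusted p = 0.00833). In the fatty acid synthesis list 6 of 15 measured genes fell and none rose, also 6 when adjusted over the list alone (camera, adjusted p = 0.00408; adjusted p = 0.41 with an estimated correlation). Srebf1, which encodes the transcription factor SREBP-1, fell from 2400 ± 587 to 991 ± 45.3 (-1.24, SE 0.15, adjusted p = 0.000744). Scd2, a desaturase, fell by 1.10 (SE 0.20, adjusted p = 0.00629).

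The gluconeogenic gene Pck1, which makes phosphoenolpyruvate, rose from 51483 ± 21339 to 211632 ± 42234 (log2 change 2.13, SE 0.30, adjusted p = 0.00166). Pcx, pyruvate carboxylase, rose by 0.67 (SE 0.11, adjusted p = 0.00448). The gluconeogenesis and glucose transport list as a whole did not pass: 4 of 16 measured genes rose and none fell, also 4 when adjusted over the list alone (camera, adjusted p = 0.12). In the list of ammonia production and acid-base transport 4 of 14 genes rose and 4 fell, the same counts as when adjusted over the list alone (camera, adjusted p = 0.83). Slc38a3, a glutamine carrier, rose from 1541 ± 355 to 4926 ± 906 (1.69, SE 0.19, adjusted p = 0.00049), and Slc7a7, a carrier of basic amino acids, fell from 4600 ± 389 to 2667 ± 354 (-0.79, SE 0.09, adjusted p = 0.00064).

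Targets of FoxO factors with insulin signalling and autophagy genes rose in 9 of 24 measured cases and fell in none, 15 when adjusted over the list alone (camera, adjusted p = 1.9e-06; adjusted p = 0.18 with an estimated correlation). Sqstm1, an autophagy receptor, rose from 13805 ± 658 to 20814 ± 2883 (0.58, SE 0.09, adjusted p = 0.00314). Of 15 genes known to respond to glucocorticoids 3 rose, 8 when adjusted over the list alone (camera, adjusted p = 0.000363; adjusted p = 0.54 with an estimated correlation). Zbtb16, a transcription factor, rose by 1.76 (SE 0.44, adjusted p = 0.0286), a call lost in 7 of 27 alternative settings (adjusted p = 0.062 without Fed 1, 0.052 without Fasted 1, 0.067 without Fasted 2, 0.081 without Fasted 3 and 0.058 without Fasted 4). Fkbp5 had 2259 ± 631 normalized counts in fed and 3690 ± 790 in fasted kidneys without passing (adjusted p = 0.0511), and passed in 9 of 27 alternative settings, among them without Fed 3 (0.027). Among NRF2 antioxidant genes 5 of 13 rose, also 5 when adjusted over the list alone (camera, adjusted p = 0.0382; adjusted p = 0.48 with an estimated correlation). Nqo1, a quinone reductase, rose from 1999 ± 546 to 3956 ± 787 (SE of the log2 change 0.18, adjusted p = 0.00651). The NRF2 call was lost in 8 of 19 alternative settings, among them without Fed 2 (adjusted p = 0.068), Fed 5 (0.11) or Fasted 4 (0.075).

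Chaperones of the endoplasmic reticulum fell in 7 of 14 measured cases and rose in none, against 9 down and 1 up when adjusted over the list alone (camera, adjusted p = 0.00064; adjusted p = 0.50 with an estimated correlation). Sdf2l1 fell from 171 ± 51.9 to 69.4 ± 18.1 (-1.28, SE 0.25, adjusted p = 0.00969) and Calr, calreticulin, by 0.82 (SE 0.19, adjusted p = 0.0197; 0.059 without Fasted 2, 0.052 without Fasted 4 and 0.051 without Fed 3 and Fasted 1). Of 23 genes of amino acid transport and breakdown 5 fell and none rose, 6 when adjusted over the list alone (camera, adjusted p = 0.00449; adjusted p = 0.26 with an estimated correlation). Gatm, which starts creatine synthesis, fell from 24224 ± 6242 to 6856 ± 786 (-1.78, SE 0.20, adjusted p = 0.00043), and Slc36a1, a proton and amino acid symporter, from 3526 ± 419 to 2125 ± 71.6 (-0.72, SE 0.08, adjusted p = 0.000459). In the vitamin D, phosphate and mineral list 3 of 14 genes fell, also 3 when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.62). Kl, which encodes the FGF23 co-receptor klotho, fell from 29829 ± 4723 to 16155 ± 1421 (-0.87, SE 0.12, adjusted p = 0.00166). The phosphate carrier gene Slc34a1 fell by 0.58 (SE 0.16, adjusted p = 0.0377), a call lost in 12 of 27 alternative settings. It was lost without each single library except Fed 5, with an adjusted p between 0.0522 without Fed 3 and 0.117 without Fasted 4.

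**Figure D2:**
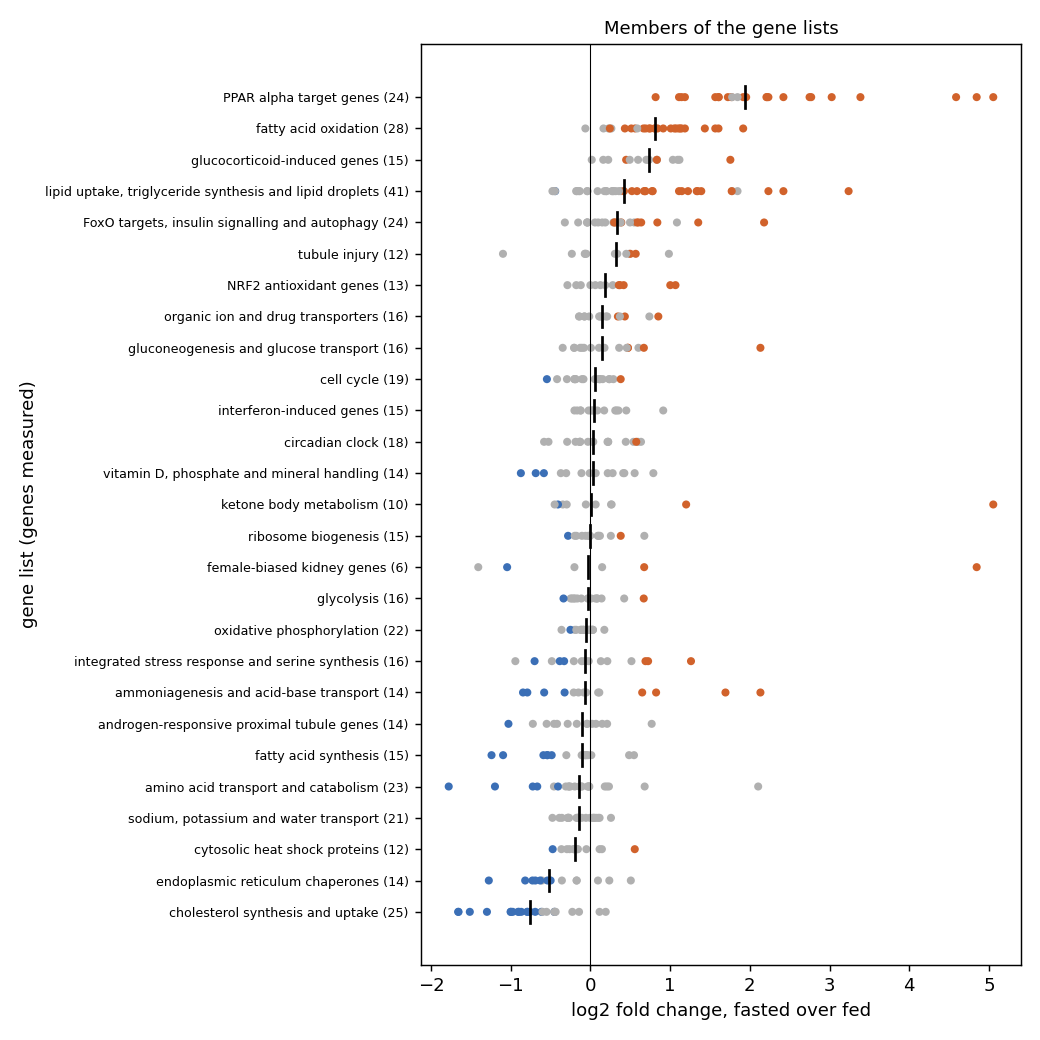
Log2 fold change, fasted over fed (horizontal axis), of each measured gene of the 27 gene lists (vertical axis, with the number of genes measured), in orange where higher and blue where lower at an adjusted p under 0.05 (limma) and grey otherwise, with the list's median as a black line. The median was 1.94 for PPAR alpha targets, 0.81 for fatty acid oxidation and -0.76 for cholesterol synthesis and uptake.

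Other large changes fell outside these lists. Acmsd, an enzyme of tryptophan breakdown that draws precursor away from NAD synthesis, fell from 3243 ± 1187 to 778 ± 169 (log2 change -1.98, SE 0.28, adjusted p = 0.00166). Col15a1, a basement membrane collagen, fell from 994 ± 140 to 347 ± 70.2 (-1.52, SE 0.14, adjusted p = 0.000154). Hsd3b4, a relative of Hsd3b2, fell by 1.77 (SE 0.33, adjusted p = 0.00817), and the Hsd3b family has near-identical copies. Among the decreases were also Pde6a, Igf2bp1 and Fam151a, with log2 changes from -1.64 to -1.44. Kcnip2, which encodes a potassium channel partner, rose by 2.54 (SE 0.36, adjusted p = 0.00176), and Aim1l by 2.63 (SE 0.46, adjusted p = 0.00546). Slc25a25, a mitochondrial ATP-Mg and phosphate carrier, rose from 4499 ± 3595 to 17345 ± 3146 (2.40, SE 0.57, adjusted p = 0.0224), and the call was lost without Fed 1 (adjusted p = 0.056), Fasted 2 (0.052), Fasted 3 (0.060) or Fasted 4 (0.065).

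The other lists did not pass with camera. The adjusted p was 0.052 for organic ion and drug transporters (3 of 16 rose), 0.16 for oxidative phosphorylation (1 of 22 fell, 0 when adjusted over the list alone), 0.27 for androgen-responsive proximal tubule genes (1 of 14 fell) and 0.27 for sodium, potassium and water transport (0 of 21 changed). It was 0.39 for cytosolic heat shock proteins (1 rose and 1 fell of 12, 1 and 2 when adjusted over the list alone), 0.40 for interferon-induced genes (0 of 15 changed), 0.49 for the circadian clock (1 of 18 rose) and 0.49 for tubule injury (2 of 12 rose). It was 0.52 for glycolysis (1 rose and 1 fell of 16, 1 and 2 when adjusted over the list alone), 0.52 for female-biased kidney genes (2 rose and 1 fell of 6) and 0.74 for the integrated stress response (3 rose and 3 fell of 16). It was 0.74 for ribosome biogenesis (1 rose and 1 fell of 15) and 0.99 for the cell cycle (1 rose and 1 fell of 19). Where no other count is given, the counts were the same when adjusted over the list alone. Oxidative phosphorylation genes passed as lower without Fed 5 (adjusted p = 0.0016) or Fed 3 (0.047), and interferon-induced genes passed without Fasted 2 (0.025). Organic ion and drug transporters passed as higher without Fed 4 (0.013), Fasted 1 (0.035) or Fasted 4 (0.039), and against all genes with a read (0.042). With clock phase as a covariate, chosen after seeing the data, they also passed (0.013), as did the circadian clock list (higher, 0.034). That covariate is the Arntl to Dbp log2 difference. Both genes are members of the circadian clock list, so the pass of that list is not an independent test. In all, 10 of the 27 lists passed, 6 higher and 4 lower, and with an estimated correlation 2 passed. Other splits of the 9 libraries passed a median of 8 lists with camera at the preset correlation. A pass alone therefore does not tell fasting from other differences between these mice. With fry the glucocorticoid (adjusted p = 0.16), endoplasmic reticulum chaperone (0.070) and NRF2 (0.056) lists did not pass, and with ranks of log2 changes the amino acid list did not (0.056). Median and mean differed in sign for ammonia production (median -0.07, mean 0.18, test lower), the integrated stress response (-0.06, 0.01, lower), ribosome biogenesis (-0.01, 0.05, higher) and female-biased genes (-0.03, 0.50, higher). They also did for the cell cycle (0.05, -0.02, lower) and the vitamin D list (0.03, -0.01, lower).

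None of the 16 marker lists with at least 2 measured genes passed with camera (smallest adjusted p = 0.20, for proximal tubule), with 1 list at an unadjusted p under 0.05, 0 with an estimated correlation and 1, lymphocyte, with fry. Without Fed 5 the proximal tubule markers passed, lower in the fasted group (adjusted p = 0.015). The adjusted p was 0.24 each for the collecting duct, intercalated cell, adipocyte, adrenal cortex and hepatocyte lists and 0.30 for lymphocytes. It was 0.44 for red blood cells, 0.47 for the thick ascending limb and endothelium, 0.63 for macrophages, 0.73 for podocytes, fibroblasts and smooth muscle, 0.78 for the distal convoluted tubule and 0.82 for thin limb and inner medulla. Brown adipocyte and skeletal muscle lists had 1 measured gene each and were not tested. Hepatocyte transcripts differed strongly between mice of the same group. Alb, albumin, had 251, 10091, 4321, 2524 and 402 normalized counts in Fed 1 to Fed 5 and 3623, 1848, 7186 and 7396 in Fasted 1 to Fasted 4.

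**Figure D3:**
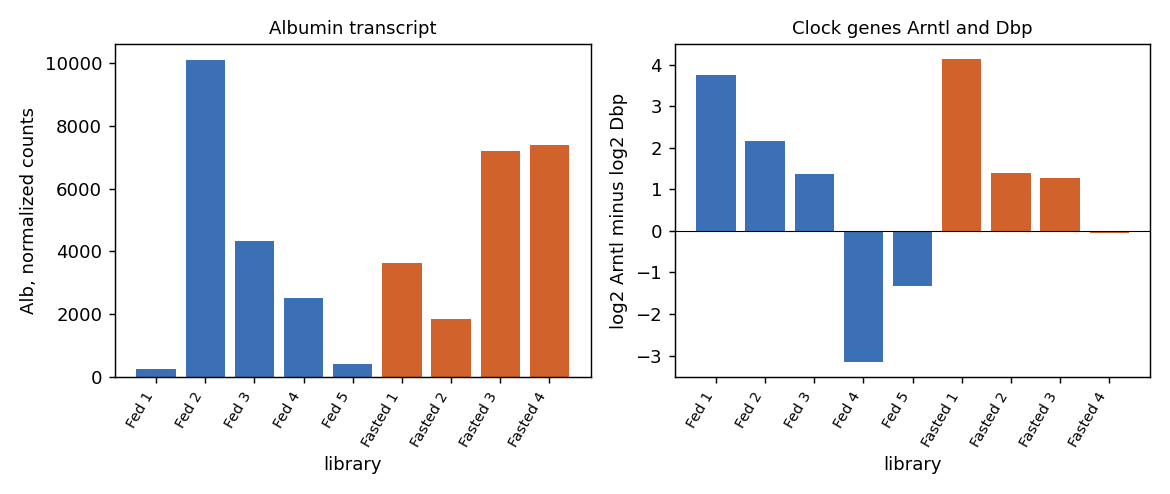
Normalized counts of Alb (left, linear axis from 0) and the log2 level of Arntl minus that of Dbp (right) in each of the 9 libraries (horizontal axes), fed in blue and fasted in orange. Alb lay between 251 and 10091 within the fed group, and the Arntl to Dbp difference between -3.15 and 3.75.

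The authors' deposited table gives 2369 genes at an adjusted p under 0.05, 1203 higher and 1166 lower, of which 1642 are among the 1656 genes above. Its fold changes are pulled towards 0: for Pdk4 the authors' deposited table has a log2 fold change of 2.32. For Cyp4a14 the authors' deposited table has a log2 fold change of 0.49 with no p-value, and for Plin2 it has 1.54, also with no p-value. Of the 705 terms that the authors' deposited annotation lists, 120 had an adjusted p under 0.05. The leading term was the peroxisome, with 40 genes and 6.09-fold enrichment (adjusted p = 2.36e-18), of which 31 were higher and 7 lower in the comparison above. Fatty acid metabolism followed the same direction with 24 of 25 genes higher, while of the 27 genes of lipid synthesis 22 were lower and 5 higher. Those terms were chosen by the authors on genes called in these same libraries, so their direction is not independent evidence.

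On GRCm38 (the mm10 build), with GENCODE M21, Hsd3b2 lies on chromosome 3 from 98709255 to 98724543. Pdk4 lies on chromosome 6 from 5483351 to 5496309, and Cyp4a14 and Cyp4a10 lie near each other on chromosome 4, from 115486200 to 115496142 and from 115518264 to 115533649. Ehhadh lies on chromosome 16 from 21761287 to 21787807, Pck1 on chromosome 2 from 173153048 to 173159273 and Gatm on chromosome 2 from 122594467 to 122611303. Each value counts reads over a gene's exons as a whole. Exons of Hsd3b2, Acmsd, Idi1, Col15a1, Lipe, Acsl1, Srebf1, Slc25a25, Slc34a1, Aim1l, Igf2bp1, Fam151a, Slc16a7, Slc7a7 and Sqstm1 overlap exons of a gene on the other strand, and whether counting kept strands apart is not stated, so the values of these genes are uncertain to that extent.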

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

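The tests on Fed 5 and those of fasting as the source of the hepatocyte and clock patterns were chosen only after the result was seen. A sample far from the others of its group was found 25 times in 250 groups of values, and 8 of these were in Fed 5. Chance gives about 12.5 for normally distributed values. The groups share the same 9 libraries, so flags can come together, and these counts alone do not show an excess over chance.

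Fed 5 had 15244 normalized counts of Cyp4a14 (other fed libraries 1070 to 1379), and Cyp4a10 was also highest there (10391). A mislabelled fasted animal is argued against by the genes at least 4-fold higher in the fasted group in a fit without Fed 5, over which Fed 5 lay at a median of 0.262 of the log2 distance from the other fed libraries to the fasted ones (quartiles 0.200 to 0.476, 15 genes). RNA of a fasted kidney would bring every gene to the same linear fraction, which was 0.268 for these 2 and 0.128 at the median of the 13 other genes (quartiles 0.0346 to 0.172). That median is only just under the bound of 0.134 set for it, so it decides little. Such RNA as the whole cause is argued against by abundant transcripts. At a share of 0.268 it alone would bring 3355 normalized counts of Pdk4 and 1363 of Angptl4, and Fed 5 had 251 and 302. Of the 13 genes 7 lay below the level that this share alone would bring. Liver RNA is argued against by Alb, at 402 in Fed 5 and a median of 3423 in the other fed libraries. A short time without food before collection may have occurred in this mouse, and this was not tested. Values go both ways. Of the 15 genes 2, Pdk4 and Angptl4, lay below the mean of the other fed libraries (664 and 789), and the rest lay above it.

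In the same library Kcnip2 had 257 normalized counts (63.3 to 79.2 in the other fed libraries), Gatm 13512 (24839 to 29651), Idi1 76.6 (229 to 342) and Pde6a 199 (438 to 597). Mvk had 267 (380 to 410), Cycs 335 (524 to 563) and Cyp2j13 5003 (8310 to 9847). Over the 67 genes at least 2-fold lower in a fit without Fed 5, it lay at a median of 0.440 of the log2 distance to the fasted libraries (quartiles 0.237 to 0.702). Over the 114 genes at least 2-fold higher it lay at 0.272 (quartiles 0.0387 to 0.489). The other fed libraries, each placed in the same way, had medians from -0.220 to 0.132 for lower genes and from -0.161 to 0.0552 for higher ones.

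Among the other fed libraries, Fed 4 had 2546 normalized counts of Scd2 (4573 to 5269 in the rest) and Fed 1 had 921 of Slc38a3 (1640 to 1827). Fed 3 had 330 of Myc (122 to 161), 6112 of Txnrd1 (4929 to 5220) and 5.53% of its counts in Rn45s (0.513% to 1.38%). Fasted 1 had 8393 of Klf9 (10454 to 10799), 670 of Cebpb (1010 to 1094), 1534 of Krt8 (2223 to 2327) and 2.36% in Rn45s (0.622% to 0.784%). Fasted 2 had 4169 of Slc25a20 (3252 to 3382), 2627 of Psat1 (1508 to 1587), 350 of Myc (224 to 238), 8060 of Txnrd1 (6681 to 6804) and 18902645 reads, or 18.9 in units of 1e6 (26.0 to 27.2 in the other fasted libraries). Fasted 3 had 641 of Mcm6 (499 to 509), and Fasted 4 had 3671 of Clock (4232 to 4301) and 1742 of Scnn1b (1517 to 1537).

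Hepatocyte transcripts differed between libraries of 1 group: the highest fed library had 40.2 times the Alb of the lowest. This argues against fasting as the source of that spread, but cannot exclude an added effect of fasting. RNA of liver carried into the libraries may account for the spread. A second list of 18 hepatocyte genes followed Alb with a median log2 slope of 0.703, just above the bound of 0.7 set before, and r = 0.990 of the list mean with Alb over the 9 libraries (exact permutation p = 1.65e-05; rho 0.967, p = 0.000165; r = 0.941 without the 2 farthest). The slopes of Apoh, Apoc3, Fga, Fgg and Apob were between 0.01 and 0.26. The labels do not say how the cortex was separated from other tissue, so the route stays open.

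Clock genes also differed within groups. The Arntl to Dbp log2 difference spanned 6.15 times as much within the fed group as the group means differed. This argues against fasting as the source of the spread, but cannot exclude a shift added by fasting. Collection at different times of day may account for the spread, though another difference in clock phase between mice would give the same pattern. With group means removed, 5 clock output genes went opposite to the mean of 2 other clock genes, Clock and Nfil3. Nfil3 ranged from 78.4 to 533 normalized counts and Clock only from 3149 to 4301, so that mean follows mainly Nfil3. Over the 9 libraries r was -0.860 (exact permutation p = 0.00301) and rho -0.85 (exact permutation p = 0.00607), with r = -0.781 without the 2 farthest. These genes belong to the circadian clock list tested above, and Clock was also a named gene, so the check is not independent of it. The Arntl to Dbp difference also went with the title numbers of the mice (r = -0.864, exact permutation p = 0.00275; rho -0.85, p = 0.00607; r = -0.819 without the 2 farthest). Within groups r was -0.937 in the fed and -0.930 in the fasted mice. Times of collection are not in the labels.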

How the results depend on the processing

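The fits without Fed 3 and Fasted 1, with edgeR, DESeq2 and TMM, and with Alb or clock phase as covariate were chosen only after the result was seen. The count of 1656 changed genes stayed within 1.5 times under other filters, pseudocounts, normalizations and tests (1319 to 2348), with 1 surrogate variable (1451), Alb (1168) or clock phase (1716) as covariate, and with Fed 1, Fed 2 and Fed 3 as the only fed mice (1803). It was 2704 with voom quality weights, 357 with Fed 4 and Fed 5 as the only fed mice and 1068 without Fed 3 and Fasted 1; the cause was not tested. Leaving out 1 library gave 861 to 1959 genes. By construction it was 538 at an adjusted p under 0.01, 2628 under 0.1 and 237 with at least a 2-fold change. The authors' terms numbered 479 at an unadjusted p under 0.05. With an estimated correlation 2 gene lists passed, against 10, since members that move together then count for less; leaving out 1 library gave 9 to 11. Of the marker lists 0 to 1 passed with 1 library left out. Of 92 called named genes, 39 kept their call in all 27 alternatives, 53 lost it in at least 1 and 0 reversed. DESeq2 size factors were not run apart, since the deposited values already carry them. With 5 and 4 mice, the simulated 2-fold changes were found in 96% of cases, and smaller ones were not simulated. That share rests on independent genes and an assumed spread, so it need not hold for these libraries.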

Other observations

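The genes of the next paragraph, and the counts of other splits for single lists, were chosen only after the result was seen.

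Neighbouring imprinted genes on chromosome 7 rose together: Peg3, a zinc finger gene, from 1044 ± 196 to 3214 ± 401 normalized counts (log2 change 1.63, SE 0.13, adjusted p = 7.73e-05, limma) and Zim1 by 2.31 (SE 0.18, adjusted p = 5.71e-05). Of 12 measured imprinted genes 2 rose, Ndn fell by 1.10 (adjusted p = 0.0094) and 9 did not pass, among them Igf2, Grb10 and Igf2r. Of 6 genes induced by bone morphogenetic protein signalling 3 rose: Id1 from 357 ± 159 to 1004 ± 121 (1.60, SE 0.28, adjusted p = 0.00598), Id3 by 1.40 (SE 0.18, adjusted p = 0.000907) and Id4 by 0.59 (SE 0.16, adjusted p = 0.0346). Id2, Smad6 and Smad7 did not pass. In Fed 5, Fos had 160 normalized counts (1098 to 1839 in the other fed libraries) and Egr1 322 (895 to 4338).

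From the 126 ways to part the 9 libraries into groups of 5 and 4, 100 splits were drawn, the real one among them. Only the real split gave as many as 1656 changed genes, and the highest other gave 142. This argues against chance for that count but does not exclude it, since 1 of 100 is the smallest share these splits can give. The other splits also mix fed and fasted mice, which widens the spread within their groups and can lower their counts. For the count of gene lists chance is not excluded: 27 of 100 splits gave 10 or more, and the highest other gave 13. The median of the other splits was 8 lists. For the marker lists the real count was 0, which each of the 100 splits reaches whatever its result (highest other 7), so that count of splits tests nothing. For single lists, these counts of splits with a camera p as small include the real split. The count was 1 of 100, the real split alone, for PPAR alpha targets, fatty acid oxidation and lipid droplets. Such a p was found in 4 for cholesterol and for FoxO targets. It was found in 8 for amino acid transport and catabolism, 10 for fatty acid synthesis, 16 for chaperones of the endoplasmic reticulum, 18 for NRF2 genes and 29 for glucocorticoid-induced genes.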
